A study of Arabidopsis thaliana with 9 samples.

How the data were processed

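The samples were 9 libraries of callus from Arabidopsis thaliana, 3 each of wild type (ecotype Col-0), a pnet1 mutant and a line that overexpresses PNET1. Per the labels' protocols, hypocotyl pieces of dark-grown seedlings spent 4 days on callus induction medium and then 10 days on shoot induction medium. Total RNA was extracted from the tissue, strand-specific mRNA libraries were made and read pairs were sequenced on an Illumina HiSeq. The labels do not say whether replicates came from separate cultures or days, so p-values measure the spread between these samples, which may be technical.

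The deposited count table holds raw counts per gene, 1 column per library, that the authors made before deposit. The submitters' processing notes name HISAT2 version 2.0.4, HTSeq version 0.6.1p1 and the TAIR10 build, without saying which step each served. The annotation release, the strand setting of the counting and any filter are not given in the sources used here. A second deposited table holds FPKM values made by the authors; each value is the count divided by the gene length and by 1 constant per library, as checked on genes with over 20 counts, and how the constant was chosen is not given in the sources used here. Both tables have 32833 genes, of which 7236 had no count in any library, and 0 rows name no gene. Start and end were the same in the TAIR10 reference annotation for 32532 of the 32548 gene identifiers found in it, so positions are TAIR10 positions. PNET1 was taken as locus AT1G07970, which the files describe as a cytochrome B561, amino-terminal protein and do not call PNET1; this match rests on background knowledge of the gene. The columns of the mutant were read as 1 allele with replicates 1 to 3.

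Counts were analysed with edgeR version 4.0.16 in R version 4.3.3. The function filterByExpr (minimum count 10, minimum total count 15) kept 19698 genes and left out 13135. Library sizes were scaled with TMM factors. All 9 libraries entered 1 quasi-likelihood fit with a mean per genotype and robust dispersion, and each comparison was a contrast in it. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed, and the count with an absolute log2 fold change of at least 1 is given beside it. Levels are in CPM with TMM scaling, as mean ± SD over 3 libraries, and SE is the standard error implied by the F statistic. Counting error is small at the level of the named genes with over 10 CPM, which rest on over 100 counts per library, and it grows for genes near 1 CPM, which rest on about 20.

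Before the data were examined, 30 gene lists were fixed for this tissue: shoot meristem and organ boundary, leaf and organ polarity, callus and wound regeneration, root meristem, root cap and root hair, endodermis and suberin, xylem, phloem, epidermis with cuticle and stomata, cytokinin response, auxin response, auxin synthesis and transport, nuclear photosynthesis and chlorophyll genes, seed maturation, flower development, DNA replication and mitosis, nucleoporins and nuclear envelope, salicylic acid defence, jasmonate, rapid stress response, abscisic acid and drought, heat shock, endoplasmic reticulum folding, low oxygen, phosphate starvation, iron deficiency, flavonoid and anthocyanin synthesis, glucosinolate synthesis, plastid-encoded genes and mitochondrion-encoded genes. Lists with at least 4 tested members were compared with all other genes by camera (limma version 3.58.1) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over 29 lists. Each list also has the number of members called when adjusted over the list alone. The rule for named genes was fixed in the same way. For each comparison it took PNET1 and the 8 largest rises and 8 largest falls (4 each for overexpression against mutant) among called genes with a gene symbol, at least 2 CPM in the higher group and no overlap between the groups' libraries, and from each list up to 4 called members with the largest change, or where fewer than 2 were called up to 2 further members with the highest level. Symbols came from the deposited table or the reference annotation, except that list members carry the symbol fixed in the list. Those sources pair 496 of the 509 named members with that symbol, and the other members were kept under the list's symbol.

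The steps were tested on simulated data. Counts were drawn around each gene's mean over all 9 libraries, and 200 genes in each line were changed by known folds. For the mutant contrast, run on 19546 genes, 68% of genes changed 1.5-fold and 94% of genes changed 2-fold were recovered, and 20 of 197 calls were false. For the overexpression contrast the same 2 shares were 68% and 91.8%, and 10 of 188 calls were false. The set test called 5 of 5 raised lists and 0 others among 30 drawn lists, all of which were simulated with genes that vary independently; the count of 0 is from camera only.

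Alternatives were other scaling factors (RLE, upper quartile, library totals only), DESeq2 version 1.42.0, no filter and a filter of at least 1 CPM in at least 3 samples, only the groups compared, robust dispersion off, a block for the replicate number, each library left out in turn, limma-trend on log2 of the deposited FPKM values with pseudocounts of 1 and 0.1, and for gene lists an estimated correlation and fry. After the data were seen, 2 more were added. In 1 of them wild-type replicate 3 and overexpression replicate 1 were left out together. The other was an offset that removes, within each library, a trend over GC content and gene length. It also removes each library's mean deviation in log2 CPM, which re-centres the library beside the TMM scaling. The effects of the alternatives are in the closing section.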

Results

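Messenger RNA was sequenced from callus, the mass of dividing cells that plant tissue forms on hormone medium, after transfer to a medium that induces shoots. The design asks what losing PNET1, a membrane protein of the plant nuclear envelope, and what raising its level does to gene expression in this tissue. Each genotype had 3 libraries. Counts assigned to genes totalled 19493969, 16890848 and 18940749 in wild type, 17287313, 16946951 and 18112167 in the pnet1 mutant, and 17915068, 17572782 and 18450951 in the overexpression line. Replicates of a genotype differed by more than counting noise, with a chi-square per degree of freedom between 2.52 and 7.65, so no library was a copy of another. This does not show whether they came from separate cultures. The first principal component held 67.7% of the variance. The mutant libraries lay between 44.4 and 51.2 on it, those of the overexpression line at -23.2, -41.0 and -44.6, and wild type at -19.2, -16.2 and -1.57. Wild-type replicate 3 and overexpression replicate 1 thus lay closest to the mutant within their groups.

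PNET1 transcript followed the genotype labels in every library. The gene (AT1G07970) has 7 exons on the minus strand of chromosome 1, positions 2469218 to 2472806 of TAIR10. Its level was 32.7, 31.4 and 28.9 CPM in wild type, 1.54, 1.12 and 1.37 CPM in the mutant and 4590, 4912 and 5215 CPM in the overexpression line, where it made up 0.492% ± 0.0311 (SD, n = 3) of all counts. The 3 mutant libraries still held 27, 19 and 25 counts. The log2 fold change was -4.52 (SE 0.10) in the mutant, with an edgeR quasi-likelihood adjusted p of 7.6e-15, and 7.31 (SE 0.07) in the overexpression line, with an edgeR adjusted p of 1.1e-21. The loci on either side did not pass the test in the mutant: PDIL5-1 had a log2 fold change of -0.06 and NF-YC10 of 0.00. AT1G07985, a gene further along at 2475226 to 2476167 that was named outside the rule after its value was seen, was lower in the mutant, at 0.798 ± 0.357 CPM in wild type and 0.229 ± 0.0625 in the mutant (log2 fold change -1.76, SE 0.48, edgeR adjusted p = 0.0099). In the overexpression line it did not pass (0.92).

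**Figure D1:**
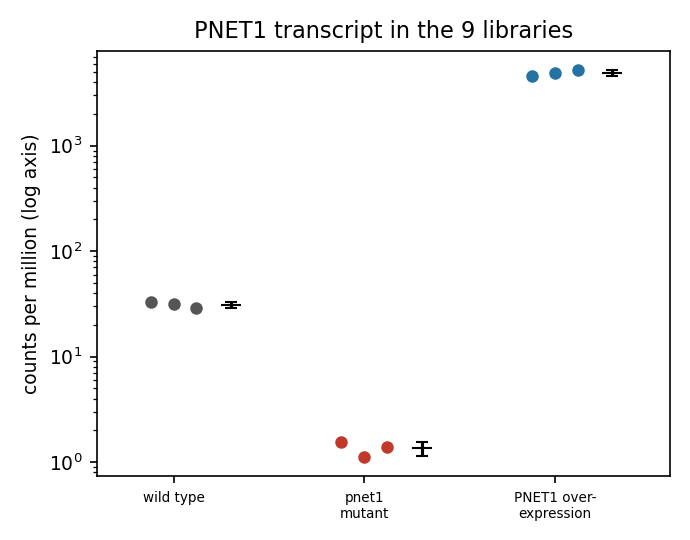
PNET1 level in CPM (log axis) in each of the 9 libraries, with the mean and SD of 3 libraries beside each genotype. The mutant libraries lie between 1.12 and 1.54, wild type between 28.9 and 32.7 and the overexpression line between 4590 and 5215.

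In the mutant, genes of photosynthesis, of the epidermis and stomata, of flavonoid synthesis and of the phosphate starvation response were lower than in wild type, and phloem genes and regulators of callus and wound regeneration were mostly higher by smaller amounts. Of these lists 41 of 41, 13 of 15, 13 of 13 and 11 of 12 genes fell and 13 of 13 and 11 of 16 rose. The camera calls had an adjusted p = 0.20 with an estimated correlation for photosynthesis, epidermis, phloem and callus, and an adjusted p = 0.082 with an estimated correlation for flavonoids and phosphate. In all, 2480 genes rose and 3428 fell of 19698 tested in the mutant against wild type. The falls were the larger changes: 1016 genes fell at least 2-fold and 79 rose at least 2-fold. The 3 mutant libraries did not overlap the 3 wild-type libraries for 8916 genes (45.3%), where chance gives 10%. With an offset for GC content and gene length, added after the data were seen, 59.2% of called genes were higher instead of 42.0%. It gave 4075 genes up and 2810 down. Because the offset also re-centres each library, this change cannot be assigned to GC content or gene length.

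Among genes that met the rule for naming, the largest falls after PNET1 itself were in SWEET11, a sugar transporter, at 2.39 ± 0.373 CPM in wild type and 0.246 ± 0.282 in the mutant (n = 3 each; log2 fold change -3.25, SE 0.60, edgeR adjusted p = 0.0018). PER64, a peroxidase of the endodermis, fell by 2.98 on the log2 scale (SE 0.69, edgeR adjusted p = 0.013; 0.052 without mutant replicate 2). LHB1B1, a light-harvesting protein, fell by 2.68 (SE 0.46), and its near-identical relatives make that value uncertain. ESP, which directs glucosinolate breakdown, fell by 2.66, the phosphate starvation phosphatase PS2 by 2.65, the nitrate transporter gene NRT2.3 by 2.64 and PNSL2, a subunit of the photosynthetic NDH complex, also by 2.64. The largest rises among genes that met the rule were smaller than these falls. CLV3, the peptide signal of shoot stem cells, rose by 1.44 on the log2 scale to 7.65 ± 1.61 CPM (SE 0.18, edgeR adjusted p = 1.7e-05). RAP2.6 rose by 1.49, NEN4 by 1.46, SDR3B by 1.31, HRE1 by 1.24, AtRLP22 by 1.23, and GA1, which makes a gibberellin precursor, and the organ growth gene ARGOS by 1.22 each on the log2 scale.

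All 41 nuclear genes of photosynthesis and chlorophyll synthesis fell, 24 of them at least 2-fold (41 also when adjusted over the list alone; median log2 fold change -1.06). GLK1, a transcription factor that drives chloroplast development, went from 24.8 ± 4.88 CPM to 5.47 ± 1.71 (log2 fold change -2.19, SE 0.28, edgeR adjusted p = 0.0012). The Rubisco small subunit genes RBCS1B and RBCS3B fell by 2.03 and 1.89 and LHCB1.1 by 1.79, with values that are uncertain because their copies are nearly identical. Of 33 tested plastid-encoded genes 17 fell and none rose (19 fell when adjusted over the list alone, median -1.13). Among them was RBCL, the Rubisco large subunit gene, with a log2 fold change of -1.95. It was at 0.913, 0.295 and 0.934 CPM in the mutant, where counts are few. Wild type had 3.27, 2.16 and 2.92 CPM and the overexpression line 1.28, 1.72 and 2.21. The plastid ribosomal RNA genes RRN16S.2 and RRN23S.1 were also called. RRN16S.2 had 3.06, 1.62 and 1.28 CPM in wild type and 0.228, 0.118 and 0.604 in the mutant. In the overexpression line it had 0.887, 0.343 and 0.539 CPM, below each wild-type library too. Over the 33 plastid-encoded genes that line had 0 rises, 2 falls and a median of -0.03. In the mutant the photosynthesis and plastid lists were both called lower by camera, with camera adjusted p = 0.20 for each with an estimated correlation. Plastid-encoded genes took 0.00563% ± 0.000811 of counts in wild type, 0.00260% ± 0.000180 in the mutant and 0.00499% ± 0.000476 in the overexpression line. The share of ribosomal RNA genes was 0.162% ± 0.0258, 0.0673% ± 0.0308 and 0.0610% ± 0.0157 in the same order (SD, n = 3). This share was thus lower in both lines than in wild type, so lower ribosomal RNA counts are not particular to the mutant.

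Of 15 markers of epidermis, cuticle and stomata, 13 fell, each at least 2-fold (14 when adjusted over the list alone; median -1.27). They included FAMA, a regulator of guard cells, at 4.23 ± 0.689 CPM in wild type and 1.16 ± 0.328 in the mutant (log2 fold change -1.86, SE 0.23, edgeR adjusted p = 1.7e-05), the stomatal regulator MUTE (-2.42), CER6, which elongates wax precursors (-1.54), and the epidermal identity regulators ATML1 (-1.27) and PDF2 (-1.23). MYB60 (-0.35) and GL1 (-0.84) did not pass. All 13 flavonoid and anthocyanin genes fell (13 when adjusted over the list alone; median -1.39). PAP1, an activator of anthocyanin genes, went from 4.34 ± 0.260 to 1.16 ± 0.190 CPM (log2 fold change -1.90, SE 0.22, edgeR adjusted p = 9.8e-06), and the biosynthetic genes 5MAT and TT7 fell by 1.84 and 1.58. Of 12 phosphate starvation genes 11 fell (12 when adjusted over the list alone; median -2.07, also with IPS1 at its bound). The phosphate transporter gene PHT1;4 went from 40.9 ± 4.12 to 8.90 ± 1.14 CPM (log2 fold change -2.20, SE 0.17, edgeR adjusted p = 2.3e-05) and MGD3, which makes galactolipids under low phosphate, fell by 2.57. The noncoding RNA IPS1 had 11 to 19 counts in wild-type libraries and 0 in every mutant library, at least 13.7-fold lower against a floor of 3 counts over the mutant group. The camera calls for these lists had an adjusted p = 0.20 with an estimated correlation for epidermis and an adjusted p = 0.082 with an estimated correlation for each of flavonoids and phosphate.

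Further lists with lower members were leaf and organ polarity, glucosinolate synthesis and abscisic acid response. Of 17 polarity regulators 10 fell and 5 rose (10 and 5 when adjusted over the list alone; median -0.97), with falls in AS2 (-1.54), YAB5 (-1.45), TCP4 (-1.36) and WOX1 (-1.20). Of 18 glucosinolate genes 9 fell and 2 rose (9 and 2 when adjusted over the list alone; median -0.36), with CYP83A1 at -1.73 and CYP79F1 at -1.68. Of 10 abscisic acid and drought genes 5 fell (5 fell and 1 rose when adjusted over the list alone; median -0.34), led by the cold- and drought-induced COR15A (-2.20) and RD29A (-1.40). The camera calls had an adjusted p = 0.28 with an estimated correlation for polarity, an adjusted p = 0.39 with an estimated correlation for glucosinolates and an adjusted p = 0.32 with an estimated correlation for abscisic acid. The abscisic acid call ended without wild-type replicate 3 (camera adjusted p = 0.073), mutant replicate 1 (0.053) or 2 (0.078), or overexpression replicate 3 (0.057).

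All 13 phloem markers rose in the mutant (13 when adjusted over the list alone; median 0.67). SEOR1, a protein of sieve elements, went from 113 ± 11.5 to 195 ± 8.63 CPM (log2 fold change 0.79, SE 0.11, edgeR adjusted p = 8.6e-04), and NAC086, a regulator of sieve element maturation, rose by 1.02. Of 16 regulators of callus and wound regeneration 11 rose and none fell (13 rose when adjusted over the list alone; median 0.54). WOX11, a homeobox regulator of root founder cells, went from 85.4 ± 3.96 to 145 ± 12.3 CPM (log2 fold change 0.77, SE 0.08, edgeR adjusted p = 6.3e-05), WIND3 rose by 0.64 and PLT3 by 0.58. The camera calls of both lists had an adjusted p = 0.20 with an estimated correlation. Of 17 salicylic acid genes 8 rose and 1 fell (9 and 1 when adjusted over the list alone; median 0.37): WRKY54 (0.69), WRKY70 (0.66) and CBP60G (0.50) rose, while the pathogenesis-related gene PR5 fell by 1.15. Of 10 rapid stress genes 7 rose (8 rose and 1 fell when adjusted over the list alone; median 0.34), among them ERF6 (0.61), and of 13 low oxygen genes 4 rose (7 when adjusted over the list alone; median 0.28), among them HRE1 and SUS4 (0.45). Of 15 auxin response genes 7 rose and 1 fell (7 and 1 when adjusted over the list alone; median 0.19), with IAA20 at 0.94, GH3.1 at 0.74 and GH3.5 at -0.58. Of 43 nucleoporin and nuclear envelope genes 9 rose, none of them 2-fold (9 when adjusted over the list alone; median 0.08), with CRWN1, a protein of the nuclear lamina, at 0.24. For these the camera calls had an adjusted p = 0.47 with an estimated correlation for salicylic acid (0.062 with fry), an adjusted p = 0.32 with an estimated correlation for rapid stress, an adjusted p = 0.23 with an estimated correlation for low oxygen, an adjusted p = 0.39 with an estimated correlation for auxin response and an adjusted p = 0.28 with an estimated correlation for nucleoporins. The auxin response call ended without wild-type replicate 1 (camera adjusted p = 0.082).

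**Figure D2:**
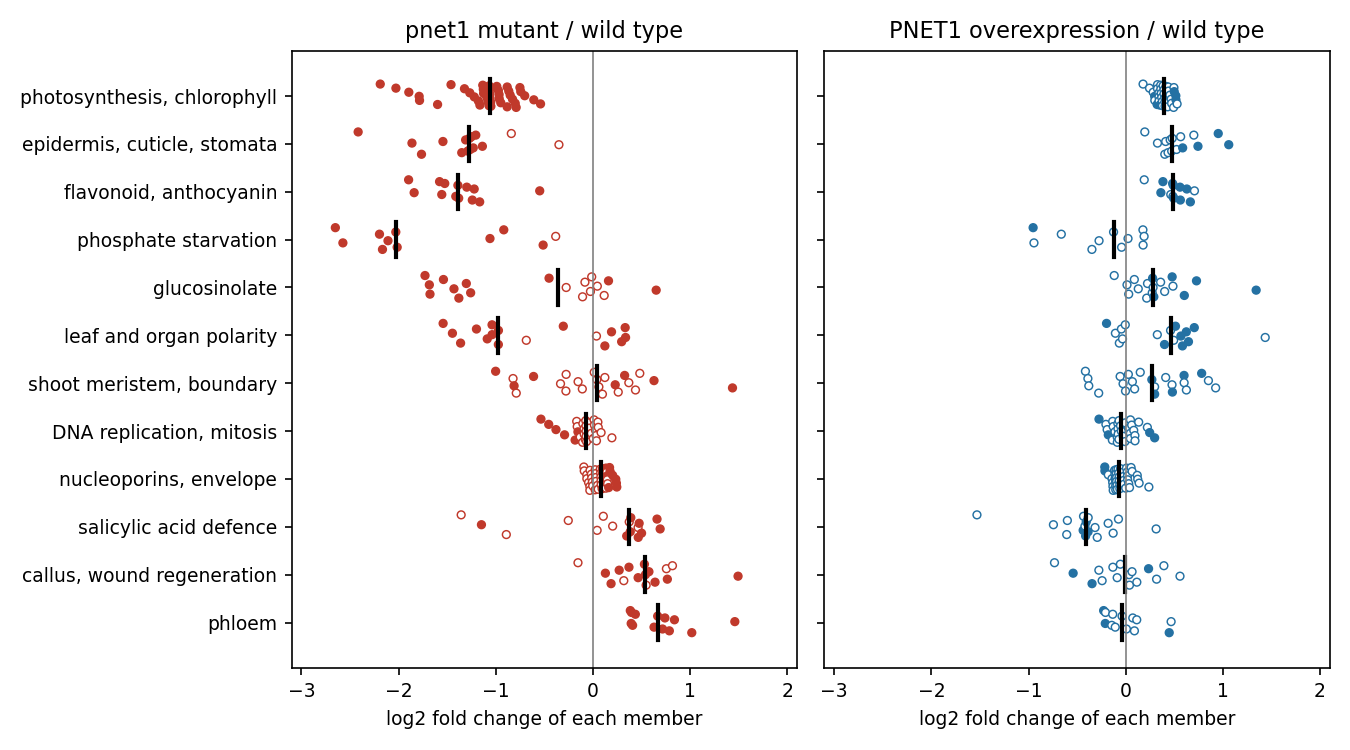
Log2 fold change against wild type of each member of 12 gene lists, in the mutant (left) and the overexpression line (right); filled points passed the edgeR test, black bars are medians and IPS1 is left out. In the mutant all 41 photosynthesis genes and all 13 flavonoid genes lie below 0 and all 13 phloem genes above it.

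Camera did not call the other lists in the mutant with all libraries. Of 23 regulators of the shoot meristem and organ boundaries 4 rose and 3 fell (4 and 3 when adjusted over the list alone; median 0.04, mean -0.03, camera direction up): CLV3 rose, ATH1 fell by 0.81, and WUS, the gene that keeps shoot stem cells, had a log2 fold change of 0.06 (SE 0.39) at about 1 CPM. Of 32 DNA replication and mitosis genes 6 fell (6 when adjusted over the list alone; median -0.07), with TSO2 at -0.29. Of 19 cytokinin response genes 4 rose and 4 fell (6 and 5 when adjusted over the list alone; median 0.07, mean -0.03, camera direction up), with CKX4 at -1.49, CGA1 at -1.23 and ARR3 at 0.99. Of 15 auxin synthesis and transport genes 6 rose and 4 fell (6 and 5 when adjusted over the list alone; median 0.00, mean -0.26, camera direction up), with TAA1 at -0.89 and YUC6 at 0.73. Of 19 jasmonate genes 4 rose and 5 fell (4 and 5 when adjusted over the list alone; median 0.02, mean -0.13, camera direction down), with LOX2 at -1.49 and ERF1 at 0.94. Of 8 endodermis and suberin genes 5 fell (6 when adjusted over the list alone; median -0.83), including ASFT at -1.19, and camera called the list lower without wild-type replicate 2 (camera adjusted p = 0.022) or overexpression replicate 2 (0.045). Of 5 root meristem genes 3 fell and 1 rose (3 and 1 when adjusted over the list alone; median -0.90), with JKD at -1.64 and SHR at 0.61. Of 17 xylem genes 3 rose (3 when adjusted over the list alone; median 0.13), with XCP1 at 0.77.

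Smaller lists added few calls in the mutant. GL2 fell (-1.47) as 1 of 8 root cap and root hair genes (1 when adjusted over the list alone; median 0.10, mean -0.04, camera direction up). Of 5 flower development genes 2 fell (2 when adjusted over the list alone; median -0.44), including PI at -0.44. Of 14 heat shock genes 2 fell (1 when adjusted over the list alone; median -0.19), including HSP23.5 at -1.20, and of 8 endoplasmic reticulum folding genes 2 fell (2 when adjusted over the list alone; median -0.09). Of 5 iron deficiency genes 0 passed edgeR or DESeq2 (0 when adjusted over the list alone; 1 at an unadjusted p under 0.05; median 0.04). Of 23 mitochondrion-encoded genes ORF107A fell (-1.07; 1 when adjusted over the list alone; median -0.01, mean -0.06, camera direction up). None of the 17 seed maturation genes had enough counts to be tested. In all, camera called 15 of 29 lists in the mutant, 7 higher and 8 lower, and 0 with an estimated correlation, where 7 had an unadjusted p under 0.05; fry called 18. The lists called by fry included some that camera did not call with all libraries. They were endodermis (fry adjusted p = 0.012), root meristem (0.016), flower development (0.0025) and DNA replication (0.033), each lower. Another split of the same 6 libraries also gave 15 camera calls, so the counts of members rest on the gene-by-gene test.

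The overexpression line had fewer changes than the mutant, and many went the opposite way: part of the flavonoid, glucosinolate, polarity and epidermis lists was higher, and part of the auxin response and salicylic acid lists lower (camera adjusted p = 0.39 with an estimated correlation for each list). The median absolute log2 fold change was 0.39 for the genes that rose and 0.29 for those that fell, against 0.32 and 0.63 in the mutant. In the overexpression line against wild type 1175 genes rose and 1033 fell, 39 and 29 of them at least 2-fold. Together they are 11.2% of the 19698 genes tested, and member counts near these shares do not set a list apart. The 2 groups' libraries did not overlap for 5585 genes (28.4%), where chance gives 10%. The count rested on single libraries. It was 368 higher and 369 lower without wild-type replicate 3, 566 and 545 without overexpression replicate 2, 468 and 476 without overexpression replicate 3, and 1970 higher without overexpression replicate 1; with only the 2 groups compared it was 763 and 667.

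After PNET1, the largest rise among genes that met the rule for naming was in CEN, a relative of the flowering repressor TFL1, at 0.887 ± 0.297 CPM in wild type and 3.15 ± 0.478 in the overexpression line (log2 fold change 1.81, SE 0.27, edgeR adjusted p = 7.5e-04). MAM3, a glucosinolate chain elongation gene, rose by 1.34, QQS by 1.28, the jasmonate and ethylene regulator ORA59 by 1.27, the apyrase gene APY5 by 1.23 and the organ size gene ORS1 by 1.13. ORS1 was higher in the mutant too, at 8.33, 8.86 and 7.42 CPM against 4.67, 4.67 and 4.04 in wild type. TZF5 had a log2 fold change of 1.36, called with all libraries (edgeR adjusted p = 0.037) and not without wild-type replicate 2 (0.060) or 3 (0.11), any mutant replicate (0.061, 0.059 and 0.057 without replicates 1, 2 and 3) or overexpression replicate 2 (0.13) or 3 (0.11). The largest falls among genes that met the rule were in CYP94B3, which inactivates jasmonate, at 2.59 ± 0.114 and 0.890 ± 0.178 CPM (log2 fold change -1.54, SE 0.26, edgeR adjusted p = 0.0019), and TOM2AH3, a tetraspanin gene (-1.53, SE 0.12, edgeR adjusted p = 1.2e-06). The mitochondrial gene ORF107A fell by 1.32, the cytokinin hydroxylase gene CYP735A2 by 1.08 and ACS8, which makes the ethylene precursor, by 1.07. ORF107A was lower in the mutant too. The mitochondrial ribosomal RNA gene RRN26 was also highest in wild type, at 140, 105 and 112 CPM, though it did not pass. It had 54.8, 39.7 and 103 CPM in the mutant and 52.2, 55.0 and 29.8 in the overexpression line. The plastid gene PSAB (-1.36, edgeR adjusted p = 0.026) lost its call without wild-type replicate 1 (0.12) or 3 (0.066) or overexpression replicate 2 (0.080) or 3 (0.12). CKX3, a cytokinin-degrading enzyme gene (131 ± 31.2 and 61.3 ± 8.75 CPM, edgeR adjusted p = 0.020), lost it without wild-type replicate 2 (0.060) or 3 (0.064) or overexpression replicate 2 (0.069) or 3 (0.085).

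In the overexpression line 9 of 13 flavonoid genes rose (11 when adjusted over the list alone; median 0.49), including CHI, at 23.7 ± 1.01 CPM in wild type and 34.9 ± 4.13 (log2 fold change 0.56, SE 0.08, edgeR adjusted p = 5.9e-04). Of 18 glucosinolate genes 6 rose (10 when adjusted over the list alone; median 0.28), including the regulator MYB28 (0.73). Of 17 polarity genes 7 rose and 1 fell (10 and 2 when adjusted over the list alone; median 0.46), including FIL (0.58). Of 15 epidermis and stomata genes 4 rose (6 when adjusted over the list alone; median 0.48), including BASL (1.06) and EPF2 (0.95). Of 41 photosynthesis genes 6 rose and none fell (30 when adjusted over the list alone, median 0.39), and DESeq2 called 25. The median log2 CPM of these 41 genes was 7.88, 7.76 and 7.30 in wild type, 6.65, 6.64 and 6.54 in the mutant and 7.78, 8.06 and 8.35 in the overexpression line, so overexpression replicate 1 lay within the wild-type range. Of 15 auxin response genes 5 fell and 1 rose (7 and 1 when adjusted over the list alone; median -0.31), with IAA30 at 21.3 ± 2.79 and 10.6 ± 0.0838 CPM (edgeR adjusted p = 1.6e-05) and IAA5 at a log2 fold change of -0.88. Of 17 salicylic acid genes 4 fell (6 when adjusted over the list alone; median -0.41), including EDS1 (-0.44) and EDS5 (-0.41). The camera calls of these lists had an adjusted p = 0.43 with an estimated correlation for photosynthesis and an adjusted p = 0.39 with an estimated correlation for each of the other 6. With fry the adjusted p was 0.080 for photosynthesis, 0.061 for epidermis, 0.053 for glucosinolates and 0.066 for salicylic acid.

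**Figure D3:**
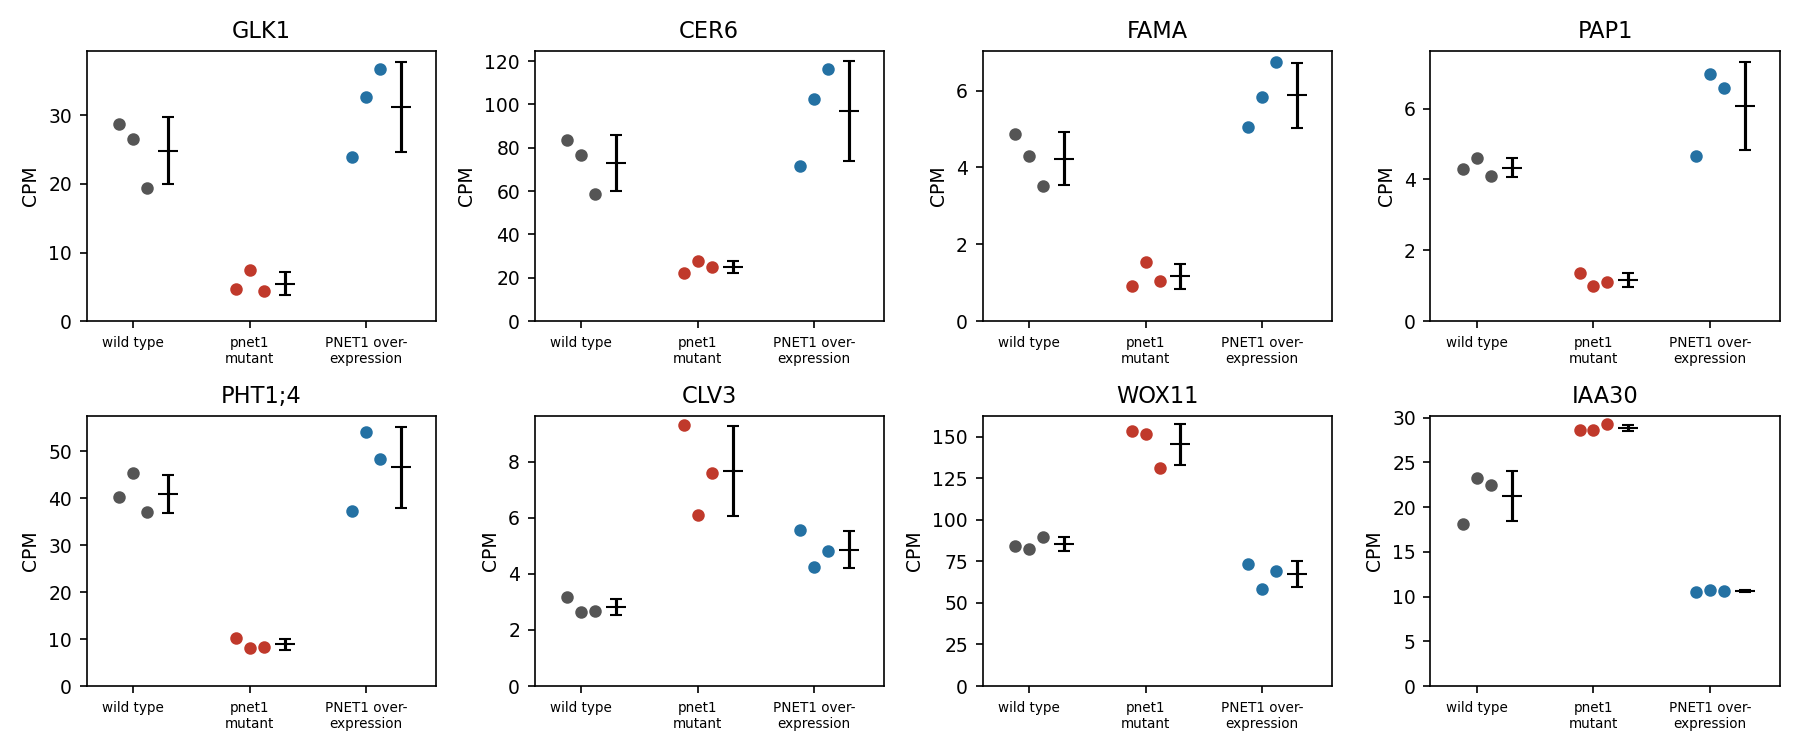
Level (CPM) of 8 genes in each library, with mean and SD of 3 libraries beside each genotype. GLK1, CER6, FAMA, PAP1 and PHT1;4 are lowest in the mutant, CLV3 and WOX11 are highest there, and IAA30 is lowest in the overexpression line (10.6 ± 0.0838).

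Another 5 camera calls in the overexpression line ended when single libraries were left out. Of 23 meristem and boundary genes 5 rose (8 when adjusted over the list alone; median 0.27; adjusted p = 0.43 with an estimated correlation; camera adjusted p = 0.12 without overexpression replicate 1). CLV3 was among them (0.78, edgeR adjusted p = 0.013; 0.060 without wild-type replicate 3), so it rose in both lines. Of 19 cytokinin response genes 7 fell and 2 rose (7 and 2 when adjusted over the list alone; median -0.14; adjusted p = 0.53 with an estimated correlation), with LBD3 at -0.42 and CGA1 at 0.63, and the call ended without wild-type replicate 2 (camera adjusted p = 0.16) or 3 (0.059), mutant replicate 3 (0.051) or overexpression replicate 2 (0.16). Of 43 nucleoporin and envelope genes 2 fell (1 when adjusted over the list alone; median -0.07; adjusted p = 0.39 with an estimated correlation), including NUP205 at -0.22 (SE 0.04), and the call ended without wild-type replicate 1 (camera adjusted p = 0.051) or 2 (0.053) or overexpression replicate 1 (0.12) or 2 (0.080). It also ended with RLE factors (0.058), library totals only (0.061), at least 1 CPM in at least 3 samples (0.065) or the GC and length offset (0.067), and without both wild-type replicate 3 and overexpression replicate 1 (0.15). The low oxygen list had 1 rise and 1 fall among 13 genes (4 and 1 when adjusted over the list alone; median 0.22; adjusted p = 0.43 with an estimated correlation), and lost its call without wild-type replicate 1 (camera adjusted p = 0.095) or overexpression replicate 1 (0.18). Of 23 mitochondrion-encoded genes only ORF107A fell (1 when adjusted over the list alone; median -0.34; adjusted p = 0.39 with an estimated correlation), and the list call ended without wild-type replicate 1 (camera adjusted p = 0.051) or overexpression replicate 2 (0.065), or with no filter on low counts (0.29). The cytokinin call also ended with library totals only (camera adjusted p = 0.051). The meristem (0.19) and low oxygen (0.063) calls also ended without both wild-type replicate 3 and overexpression replicate 1. Camera called 12 of 29 lists, 7 higher and 5 lower, and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05; fry called 6, and another split of the same libraries gave 15 camera calls.

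The other lists were not called by camera in the overexpression line with all libraries. Rises and falls, with the numbers adjusted over the list alone in brackets, were 1 and 2 (1 and 4) for callus and wound genes, 3 and 1 (3 and 1) for root meristem, 1 and 2 (1 and 2) for phloem, 2 and 1 (2 and 3) for auxin synthesis and transport, 1 and 0 (2 and 0) for flower development and 2 and 2 (2 and 3) for DNA replication. They were 3 and 3 (4 and 5) for jasmonate, 0 and 1 (0 and 1) for rapid stress, 1 and 2 (2 and 2) for abscisic acid, 0 and 1 (0 and 1) for endoplasmic reticulum folding, 0 and 2 (0 and 2) for phosphate starvation, 0 and 1 (0 and 1) for iron deficiency and 0 and 2 (0 and 2) for plastid-encoded genes. In edgeR 0 genes passed of 8 for root cap, 8 for endodermis, 17 for xylem and 14 for heat shock, where 2, 2, 3 and 2 had an unadjusted p under 0.05 and DESeq2 called 0, 0, 1 and 1. Median and mean differed in sign for phloem (-0.04 and 0.01) and jasmonate (-0.13 and 0.04), and the abscisic acid list had a median of 0.12 and a camera direction down. Camera called the callus list lower without overexpression replicate 1 (camera adjusted p = 0.0086), flower development higher without wild-type replicate 3 (0.036), and as lower rapid stress without wild-type replicate 2 (0.0087) or overexpression replicate 1 (0.033), phosphate without wild-type replicate 3 (0.044) or overexpression replicate 2 (0.0018) or 3 (0.043), and iron without wild-type replicate 2 (0.0068) or overexpression replicate 3 (0.032).

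At 1 place on chromosome 2, named outside the rule and after its values were seen, 2 adjacent genes changed in the overexpression line. AT2G20725, a gene without a symbol at 8933317 to 8935496 on the minus strand, had the largest rise after PNET1. Its level was 16.6, 18.6 and 18.1 CPM in wild type, 15.7 ± 1.09 in the mutant and 268 ± 4.26 in the overexpression line (log2 fold change 3.92, SE 0.06, edgeR adjusted p = 4.4e-19). TOM2AH3 starts 40 bases beyond its upstream end on the plus strand (8935537 to 8937554), at 13.6 ± 1.15, 14.2 ± 0.232 and 4.71 ± 0.698 CPM. Of the 26 other tested genes within 50 kb, 0 changed 2-fold and 1 passed the edgeR test, with log2 fold changes from -0.72 to 0.42.

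**Figure D4:**
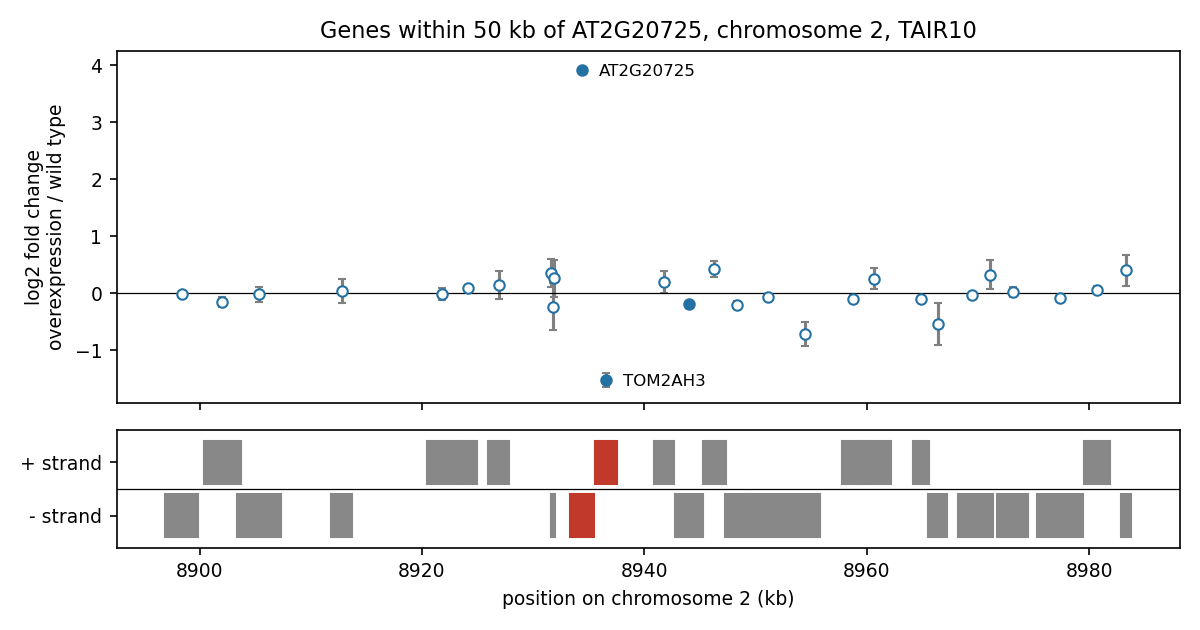
Log2 fold change with SE in the overexpression line against wild type of the tested genes within 50 kb of AT2G20725 on chromosome 2, above a map of the genes by strand. AT2G20725 lies at 3.92, TOM2AH3 at -1.53 and the 26 others between -0.72 and 0.42.

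Changes in the overexpression line ran against those in the mutant. Across the 19698 genes, which are not independent replicates, the log2 fold changes of the lines against wild type had a Pearson r of -0.321 and a Spearman rho of -0.300. Unchanged groups were simulated around the wild-type means and shared 3 drawn wild-type libraries, with genes that vary independently. They gave a mean r of 0.499 (0.480 to 0.555 over 20 draws). Variation that many genes share between libraries is absent from the draws, so this range is no bound for groups that differ in it. The covariance was -0.0433 against a simulated 0.0135, a difference of -0.0569. Of 1330 genes called in both lines 1198 changed in opposite directions. There were 777 genes lower in the mutant and higher in the overexpression line, where independent lists give 204, and 421 with the reverse pattern, where independent lists give 130. In the same direction, 65 genes were higher in both (148 for independent lists) and 67 lower in both (180); simulated unchanged groups gave means of 0.15 and 0.10 for these and 0 for opposite calls, a count of edgeR calls at the adjusted threshold only. The 3 wild-type libraries could not be divided into parts of at least 2 libraries, and shared controls push the lines in the same direction, where fewer genes were called than independent lists give. Libraries also varied within a genotype along the fold change between the other genotypes. The absolute r of this was over 0.3 in 3 of 9 libraries, and simulated values reached 0.0273. They were wild-type replicate 3 (-0.431) and overexpression replicates 1 (0.486) and 3 (-0.312). A state of the cultures that varies in this way cannot be told apart from an effect of PNET1 in the opposite changes. The r between the lines was -0.174 without wild-type replicate 3. With no filter on low counts it was 0.298, since the 5899 genes added, at a median of 0.0490 CPM, had an r of 0.428 and the other genes -0.321; simulated unchanged groups without the filter gave 0.497.

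**Figure D5:**
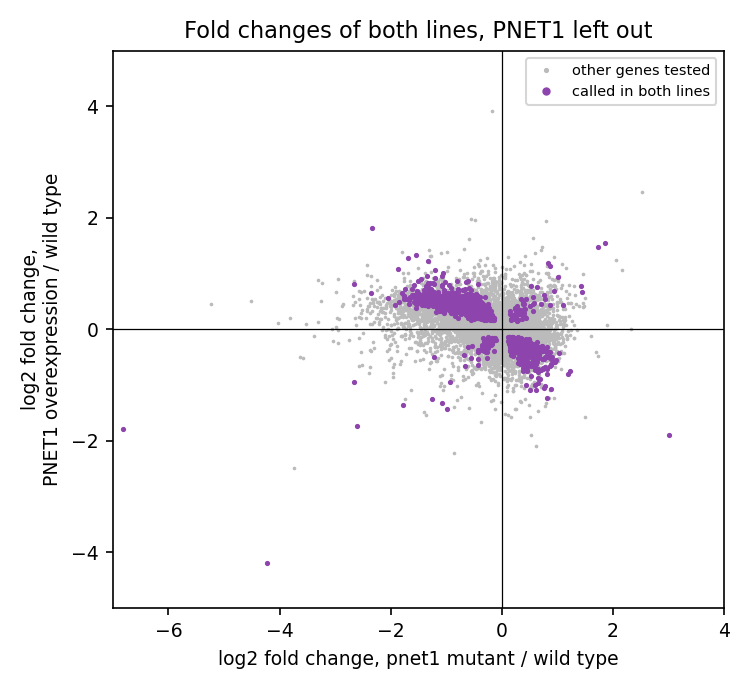
Log2 fold change against wild type of each tested gene except PNET1, in the mutant (horizontal) and the overexpression line (vertical); purple points were called in both. Of the 1330 genes called in both (PNET1 included), 1198 lie in the quadrants of opposite direction.

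The direct comparison of the overexpression line with the mutant gave the most changes, 4524 genes higher and 4052 lower, with 1774 and 334 at least 2-fold. These are 43.5% of the genes tested. After PNET1 (log2 fold change 11.82, SE 0.09, edgeR adjusted p = 4.7e-23) the largest rises among genes that met the rule for naming were in CEN (4.15, SE 0.37), the transporter gene ABCB13 (4.07, SE 0.49) and SWEET11 (3.76, SE 0.57). The largest falls among genes that met the rule were in the glutaredoxin gene GRXC14, at 16.4 ± 1.74 CPM in the mutant and 4.08 ± 0.462 in the overexpression line (log2 fold change -2.00, SE 0.14, edgeR adjusted p = 1.4e-08), and in GA1 (-1.98), ACS8 (-1.96) and MYB101 (-1.81). All 41 photosynthesis genes rose (41 when adjusted over the list alone, median 1.47). So did 14 of 15 epidermis genes (15, median 1.87) and 13 of 13 flavonoid genes (13, median 1.96), where the second number is again adjusted over the list alone. Of 12 phosphate genes 10 rose (10, median 1.72), while against wild type 0 rose and 2 fell in the overexpression line (median -0.20). Phloem genes fell (12 of 13; 12 when adjusted over the list alone), as did 11 of 16 callus and wound genes (11) and 13 of 17 salicylic acid genes (13), of which 1 rose. Camera called 13 of 29 lists, 7 higher and 6 lower, and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05; fry called 20, and another split of the same libraries gave 16 camera calls. Polarity (11 rose and 5 fell), glucosinolates (14 and 2) and plastid-encoded genes (16 and 0) were also called higher, and auxin response (2 and 10), rapid stress (0 and 9) and nucleoporins (1 and 19) lower. The plastid call ended with no filter on low counts (camera adjusted p = 0.16), with at least 1 CPM in at least 3 samples (0.11) and without both wild-type replicate 3 and overexpression replicate 1 (0.10). The adjusted p with an estimated correlation was 0.21 for flavonoids, 0.28 for salicylic acid and rapid stress and 0.27 for each of the other 10 lists called. With the offset for GC content and gene length the split moved from 52.8% higher to 36.7% higher, with 3815 genes up and 6594 down. The offset also re-centres each library, so this move cannot be assigned to GC content or gene length.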

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

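The 2 alternatives chosen after the data were seen are the offset for GC content and gene length and the fit without both wild-type replicate 3 and overexpression replicate 1. PNET1 kept its direction and its call in all alternatives. For the mutant against wild type, the counts of genes higher and lower stayed within 1.5 times under each alternative except the offset for GC content and gene length, which gave 4075 higher, 2417 of them among the 2480; in overexpression against mutant it gave 6594 lower, 3955 of them among the 4052. The cause was not tested. For overexpression against wild type, fits without 1 library gave 368 to 1970 genes higher (368 without wild-type replicate 3, 1970 without overexpression replicate 1) and 369 to 1155 lower; only the 2 groups compared gave 763 and 667, and limma-trend on log2(FPKM + 1) without a filter gave 399 and 407, and the cause was not tested. Without both wild-type replicate 3 and overexpression replicate 1 the counts were 1448 and 773, of which 922 and 616 were among the main calls. With an estimated correlation 0, 0 and 0 lists were called in the 3 comparisons (7, 3 and 5 at an unadjusted p under 0.05; camera), and fry, which asks whether a list's genes move one way, called 6 in overexpression against wild type (4 shared with camera) and 20 in overexpression against mutant (13 shared). The correlation between the lines' fold changes was 0.298 with no filter on low counts, through the low genes added, -0.393 with at least 1 CPM in at least 3 samples, and between -0.399 and -0.174 without 1 library.

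Of named genes called, 90 of 109 in the mutant, 27 of 83 in the overexpression line and 7 of 7 between the lines kept their call. This holds for the alternatives that tested the gene, where 0 turned direction. Some alternatives left out some genes: between the lines ABCB13 was tested in 21 and GA1 in 23. The replicate numbers did not pair the libraries: the 9 same-numbered pairs had correlations of -0.176 to 0.0768, and 2 of 9 samples correlated best with their own number. With a replicate block the counts were 2373 higher and 3310 lower in the mutant, 908 and 818 in the overexpression line and 4428 and 3938 between the lines, with 15, 11 and 14 lists called. Depth limits genes near 1 CPM, about 20 counts per library, where SE values reach 0.3 or more on the log2 scale.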

Other observations

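The tests of epidermal cells and of the locus on chromosome 2, and the choice of the genes in this paragraph, which have no symbol, came after their values were seen. AT1G06957, a noncoding RNA gene at 13477922 to 13478204 on chromosome 1, had 4.55 ± 0.758 CPM in wild type, 6.28 ± 0.216 in the overexpression line and 0.116 ± 0.104 in the mutant (n = 3; log2 fold change -5.24, SE 0.34, edgeR adjusted p = 4.7e-08). AT1G75945, a protein-coding gene at 28515245 to 28515916 on chromosome 1, went the opposite way in the lines: 1.54 ± 0.118 CPM in wild type, 12.4 ± 1.07 in the mutant (log2 fold change 3.01, SE 0.16, edgeR adjusted p = 2.5e-09) and 0.408 ± 0.0738 in the overexpression line (-1.90, SE 0.28, edgeR adjusted p = 6.6e-04). AT5G26270 on chromosome 5 was lower in both lines, with 59.5, 14.9 and 32.2 CPM in the wild-type libraries, 1.91 ± 0.418 in the mutant (log2 fold change -4.23, SE 0.67) and 1.94 ± 0.697 in the overexpression line (-4.20, SE 0.66; edgeR adjusted p = 0.0041 and 0.014).

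The rise of AT2G20725 beside the fall of TOM2AH3 was weighed against 2 explanations. Reads of PNET1 counted at AT2G20725 are argued against, since the exons share 0 words of 25 bases. A local change in this line, such as an insertion, stays open, since the random draw made for it cannot decide it. A draw of 29 genes at random put a lowered gene beside AT2G20725 in 0.302% of 100000 draws, but the place was picked because the genes are adjacent, so this decides nothing.

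The lower photosynthesis, epidermis, flavonoid and phosphate lists in the mutant have 81 members with a median log2 fold change of -1.21. Library scaling is argued against, since the median reached at most -1.18 under 3 other scalings. With the offset for GC content and gene length the fall remained, at a median of -1.06. That offset moved all genes by a median of 0.0725, but it also re-centres each library. These values therefore do not isolate a GC or length trend, and its share in the fall stays open. A state of the cultures that also varies within a genotype, such as how far shoots have formed, cannot be told apart from an effect of PNET1: the deviation of a library from its genotype mates correlated across genes with the fold change between the other genotypes at an absolute r over 0.3 in 3 of 9 libraries (wild-type replicate 3, r = -0.431; overexpression replicate 1, 0.486, and 3, -0.312), simulated values reached 0.0273, and mutant libraries stayed between -0.0804 and 0.0760. What keeps it open is that 3 libraries per genotype, whose cultures the labels do not describe, do not separate line from state. The genotype itself stays among the open explanations.

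A lower share of epidermal cells in the mutant cultures stays open and was not decided by the tests run. ATML1, PDF2, PDF1, FDH, LTP1 and CER6 had a mean log2 fold change of -1.28 with an SD of 0.137 between genes, but these 6 were picked from the epidermis list after their values were seen, and the whole list spans -2.42 (MUTE) to -0.35 (MYB60). The phosphate starvation list, with a median of -2.07, lay below the lowest of the 6 (-1.54) by more than their largest SE (0.247). That met the condition written against the explanation, after the values were seen. A further condition, a median below every member of the epidermis list by its SE, was not met, since MUTE fell further still. MUTE had 0.0570, 0.236 and 0.385 CPM in the mutant, where counts are few, so the phosphate list leaves the question undecided. No cell counts or images were used here.

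With 3 libraries per group there are 10 splits of the 6 libraries in a comparison, too few for a share under 0.05. The real split gave 5908 changed genes in the mutant, 2208 in the overexpression line and 8576 between the lines, each the highest, so 1 of 10 splits gave as many; the highest other split gave 0, 1 and 0 edgeR calls, and up to 754, 2668 and 747 genes at an unadjusted p under 0.05. The split with 2668 put wild-type replicate 1 with overexpression replicates 2 and 3. Every other split mixes the genotypes within its groups, so their difference widens the spread there and lowers the edgeR calls. The low edgeR counts of those splits are therefore no support for the real one. For camera calls the real splits gave 15, 12 and 13 lists and the highest other 15, 15 and 16, with 2, 2 and 4 of the 10 splits giving as many.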
